A study of Arabidopsis thaliana with 24 samples.

How the data were processed

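RNA sequencing of 24 Arabidopsis thaliana libraries was examined, each made from total RNA extracted with TRIzol. At 12 days of age, seedlings grown on plates of Murashige and Skoog medium gave 15 libraries of 5 genotypes (wild type, nasp, hag2 nasp, msi2 msi3 nasp and hag2 msi2 msi3, 3 libraries each), read on a DNBSEQ instrument from one end over 50 bp. At 20 days, plants from a growth chamber gave 9 libraries of 3 genotypes (wild type, msi2 msi3 and hag2 msi2 msi3, 3 libraries each), read on a NovaSeq instrument from both ends over 150 bp. Plants grew under 16 h of light and 8 h of dark at 22 °C. Nothing in the labels says whether replicates were grown or harvested separately, so p-values measure only the spread between these samples. HAG2, MSI2, MSI3 and NASP encode a type B histone acetyltransferase, a pair of WD40 histone-binding proteins and a histone chaperone, called here the NuB4 genes.

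The submitters' notes name bcl2fastq, HISAT2, edgeR and the TAIR10 genome build, without versions; the read counter and the annotation were not given in the sources used here. The deposited tables hold signal, normalized gene-level read values that are not whole numbers, which the authors brought to 19.6 to 21.0 M per library at 12 days and 45.7 to 48.2 M at 20 days. The median of the values near 1 was 0.871 to 1.13 per library, which does not measure the step of 1 read. Read counts were not recovered, and the number of reads behind a value is unknown. Each table lists 32548 genes, all of which matched a locus tag of the reference (TAIR10.1). In the 20-day table, 72771 cells at the rounding floor were set to 0. Organelle genes are not among those listed, and transposable element genes were not analysed as a class. The strand of the libraries was not stated, so values of antisense and long noncoding RNAs are less certain than others. Values of near-identical gene copies such as the histone genes are less certain too, because how reads matching several copies were counted was not given.

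Values were taken as log2(value + 1). Genes with a value of at least 1 in at least 3 libraries were tested, 24305 at 12 days and 23707 at 20 days. limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3 was fitted to all groups of one age together, and the ages were fitted apart. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The difference between ages was tested as an interaction in a fit of the wild type and hag2 msi2 msi3 libraries of both ages (21893 genes). A plan for counts had been written before the data were examined, together with a fallback for values that are not counts; the fallback was used. Group values are means ± SD over n = 3 libraries, and log2 fold changes are given ± the standard error of the fit.

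Before the data were examined, 28 gene lists holding 427 genes were fixed: NuB4 complex genes, other histone acetyltransferases and histone chaperones, histone H3 and H4 genes, salicylic acid and immune response, jasmonate response, abscisic acid and drought response, cold response, heat shock proteins and factors, unfolded protein response, DNA damage response, DNA replication and cell cycle, nuclear photosynthesis genes, ribosomal proteins and ribosome biogenesis, floral integrators and flower meristem or organ identity, floral repressors, the morning-phased and the evening-phased circadian clock, anthocyanin and flavonoid synthesis, glucosinolate synthesis, iron deficiency response, phosphate starvation response, leaf senescence, genes silenced by DNA methylation or heterochromatin, seed maturation, rapid touch and wound response, auxin and cytokinin early response, root markers, and anther and pollen markers. The root and the anther and pollen lists stood in for organ makeup. The NuB4 list holds the mutated genes themselves, so its fall in a mutant follows largely from the genotype and is no independent result. Each list was compared with all other genes by limma's camera, with a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data. The plan assumed voom-type values for camera; log2(value + 1) was used instead. At 20 days the lists of silenced genes and of seed maturation had too few measured members and were not tested. Beside the counts over all genes tested, calls adjusted over the list alone are given.

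The genes named were chosen by a rule fixed at the same time: the 4 NuB4 genes; the 6 risen and 6 fallen genes with the largest change against a wild type, or 4 and 4 between mutants and between ages, among called genes with a mean of at least 5 in the higher group and no overlap between the groups; and, for each called list, the 3 members with the lowest adjusted p. Of the called genes taken by this rule, those whose call ended under any alternative or without any 1 library are left out of the text, apart from 2 defensin genes at 20 days and between ages, given because they are named at 12 days; this exclusion was chosen after the values were seen. It kept 28 of 40 genes in nasp, 27 of 40 in hag2 msi2 msi3 at 12 days, 48 of 59 in msi2 msi3, 27 of 39 in hag2 msi2 msi3 at 20 days, 12 of 23 in the comparison of these mutants at 20 days, 7 of 27 in the difference between ages, and all in the comparisons of hag2 nasp and msi2 msi3 nasp.

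Alternatives were no filter on low values, a filter of at least 1 CPM in 3 libraries, a pseudocount of 0.1, only the groups compared, the replicate number as a block, each library left out in turn, an estimated correlation and limma's fry for the lists, and an adjusted p below 0.01 for shared calls. Median-ratio scaling, robust empirical Bayes and voom weights were added after the data were seen. The voom setting also divides each library by its total, so it changes the scaling as well as the weights. Correlations and covariances of changes were compared with 50 simulated data sets that share their control libraries, and the histone list with 10000 random lists matched on exon length and expression. The procedure was tested on simulated data in which 200 genes were changed: 32.8 to 68.7% of genes changed 1.5-fold, 61.2 to 85.1% of those changed 2-fold and 69.7 to 92.4% of those changed 4-fold were called, with 4 to 11 unchanged genes called per comparison. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.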

Results

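Gene expression was measured in Arabidopsis plants mutated in combinations of HAG2, MSI2, MSI3 and NASP, to ask what the acetyltransferase, histone-binding and chaperone parts of the NuB4 complex do apart and together. There were 5 genotypes at 12 days and 3 at 20 days, with 3 libraries each (24 in all). Deposited values summed to between 19.6 and 21.0 M per library at 12 days and between 45.7 and 48.2 M at 20 days. In a principal component analysis at 12 days, the first component held 74.2% of the variance and parted the hag2 nasp and msi2 msi3 nasp libraries from those of the wild type, nasp and hag2 msi2 msi3. At 20 days the first component held 26.0% and parted the wild type from both mutants. No hag2 plants without another mutation were sequenced, so the interaction of hag2 with nasp cannot be tested. That of msi2 msi3 with nasp cannot be tested either, because msi2 msi3 was sequenced only at 20 days and the nasp genotypes only at 12 days.

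The transcripts of the mutated genes were lowered in most, not all, of the groups named after them. NASP (AT4G37210; chromosome 4, 17512254 to 17514723 in TAIR10.1), a histone H3 chaperone, stood at 512 ± 31.0 in the wild type and at 30.0% of that in nasp, 26.1% in hag2 nasp and 27.2% in msi2 msi3 nasp. HAG2 (AT5G56740; chromosome 5, 22952767 to 22955739) stood at 17.9% of the wild type in hag2 msi2 msi3 and 6.43% in hag2 nasp at 12 days, and at 14.2% in hag2 msi2 msi3 at 20 days. MSI3 (AT4G35050; chromosome 4, 16682580 to 16684928) stood at 16.2% in hag2 msi2 msi3 and 30.8% in msi2 msi3 nasp at 12 days, and at 16.7% and 17.7% in hag2 msi2 msi3 and msi2 msi3 at 20 days. MSI2 (AT2G16780; chromosome 2, 7281374 to 7283686) stood at 45.3% in msi2 msi3 nasp and 46.2% in msi2 msi3. In the libraries labelled hag2 msi2 msi3 MSI2 stood at 92.9% at 12 days (adjusted p = 0.578) and 82.1% at 20 days (adjusted p = 0.0692), a difference from the wild type that did not pass the test at either age, and at 20 days MSI2 was higher than in msi2 msi3 by 0.83 ± 0.08 on the log2 scale (adjusted p = 1.22e-04). What follows for these libraries is given under their label. Where they were not mutated, HAG2 stood at 167% of the wild type in msi2 msi3 nasp and MSI3 at 150% in hag2 nasp.

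**Figure D1:**
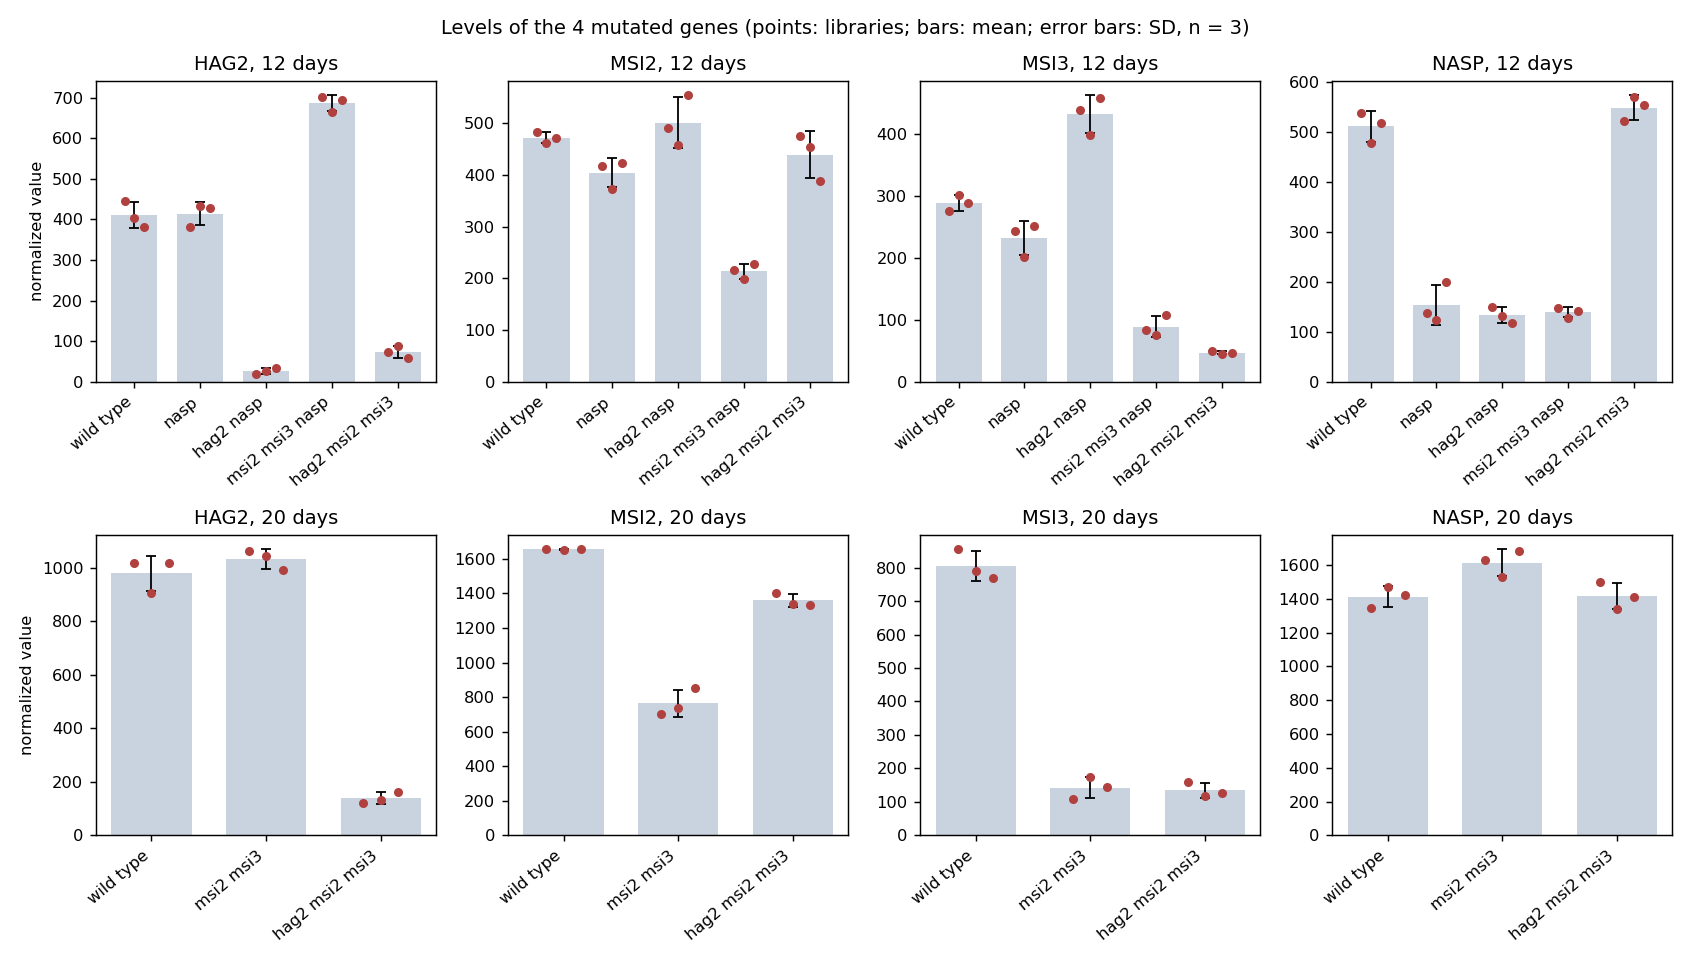
Normalized value (y axis) of HAG2, MSI2, MSI3 and NASP in each genotype at 12 and 20 days; bars are means, points are libraries and error bars are SD (n = 3). MSI2 in hag2 msi2 msi3 stands at 439 at 12 days and 1359 at 20 days, against wild type values of 472 and 1655.

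Histone H3 and H4 genes rose in each mutant group. Of the 17 genes, 15 rose and 0 fell in each of the 6 comparisons with a wild type, and 15 to 17 rose when adjusted over the list alone. The median log2 fold change was 0.82 in nasp, 1.73 in hag2 nasp, 1.90 in msi2 msi3 nasp and 0.83 in hag2 msi2 msi3 at 12 days, and 0.74 in msi2 msi3 and 0.60 in hag2 msi2 msi3 at 20 days. The H4 gene AT3G53730 went from 1075 ± 31.5 in the wild type to 2890 ± 179 in nasp and 8073 ± 535 in hag2 nasp. The H3.3 gene AT5G10980 rose by 1.13 ± 0.06 in nasp, 2.09 ± 0.06 in hag2 nasp, 0.93 ± 0.06 in hag2 msi2 msi3 at 12 days and 1.04 ± 0.06 in msi2 msi3 at 20 days (log2). CENH3, the centromeric H3, passed the test in none of the 6 comparisons; the other gene that did not pass was AT1G07660 in 4 of them and AT4G40030 in both nasp combinations. The list test gave adjusted p = 1.42e-36 in nasp, 4.04e-38 in hag2 msi2 msi3 at 12 days, 1.27e-30 in msi2 msi3 and 7.59e-29 in hag2 msi2 msi3 at 20 days, and these calls held with an estimated correlation. In hag2 nasp (adjusted p = 2.81e-09) the call did not hold, at adjusted p = 0.199 with an estimated correlation. In msi2 msi3 nasp (adjusted p = 1.70e-09) it did not hold either, at adjusted p = 0.195 with an estimated correlation.

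**Figure D2:**
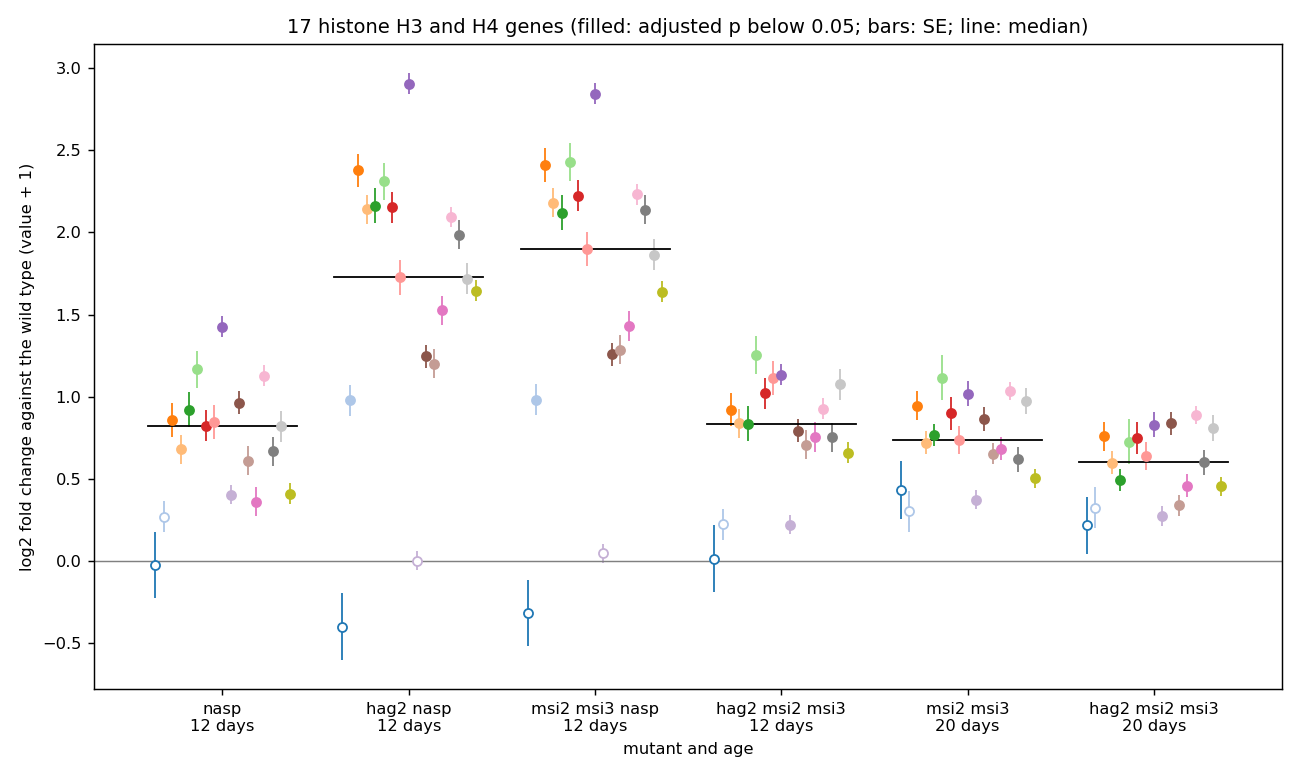
Log2 fold change against the wild type (y axis) of the 17 histone H3 and H4 genes in the 6 mutant groups; points are genes with the standard error of the fit, filled where the adjusted p is below 0.05, and the black line is the median. The medians run from 0.60 in hag2 msi2 msi3 at 20 days to 1.90 in msi2 msi3 nasp.

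In nasp seedlings, most genes of the morning clock list rose and most of the evening clock list fell. HIS1-3, the stress-induced linker histone H1.3, went from 444 ± 82.0 to 2386 ± 133 (log2 fold change 2.44 ± 0.10, adjusted p = 1.46e-10). The cold-response factor CBF2 rose by 1.99 ± 0.26, AT1G07450 by 2.31 ± 0.25, and AT3G06955, annotated as another RNA, by 2.51 ± 0.44 (log2). AT3G01345 fell by 5.46 on the log2 scale, from wild type libraries at 456, 151 and 677 to a mean of 7.23 in nasp. PAP5, a purple acid phosphatase, fell by 3.16 and AT5G24215 fell by 2.82 on the log2 scale. AT2G04885 was listed at 0 in the wild type and AT2G03821 at 0 in nasp. In all, 945 of 24305 genes changed, of which 608 rose and 337 fell, and 83 and 43 of these did so at least 2-fold.

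Of the 8 morning-phased genes 7 rose and 1 fell in nasp (median 1.09, adjusted p = 5.65e-09), with the same counts when adjusted over the list alone. CCA1 rose by 1.61 ± 0.19 and LNK2 by 1.08 ± 0.09, while RVE2 fell by 0.91 on the log2 scale. Of the 8 evening-phased genes 5 fell, and 6 fell and 1 rose when adjusted over the list alone (median -0.29, adjusted p = 2.80e-06). PRR3 changed by -0.64 ± 0.09 and TOC1 by -0.44 ± 0.07. No hour of harvest was available here, so its effect on clock genes cannot be told apart from that of genotype in any comparison. The calls of the histone, morning and evening lists held with an estimated correlation; those of the 9 other called lists did not. Of 37 nuclear photosynthesis genes 12 rose, and 18 rose and 1 fell when adjusted over the list alone (median 0.25, adjusted p = 7.24e-19, adjusted p = 0.185 with an estimated correlation). The light-harvesting genes LHCB1.1, LHCB2.1 and LHCB2.2 rose by 1.37 ± 0.11, 0.98 ± 0.09 and 0.85 ± 0.10. Of 15 phosphate starvation genes 5 fell, and 11 when adjusted over the list alone (median -0.55, adjusted p = 5.15e-10, adjusted p = 0.142 with an estimated correlation). The phosphatase gene PS2 changed by -1.28 ± 0.24. Of 18 iron deficiency genes 4 rose, and 9 rose and 1 fell when adjusted over the list alone (adjusted p = 2.85e-05, adjusted p = 0.271 with an estimated correlation). NAS4 changed by 0.57 ± 0.09. Of 10 touch and wound genes 3 rose, and 5 when adjusted over the list alone (adjusted p = 5.05e-05, adjusted p = 0.271 with an estimated correlation). ZAT10 changed by 1.28 ± 0.16 and TCH2 by 0.74 ± 0.12. In the unfolded protein response list 3 of 9 fell, and 4 when adjusted over the list alone (adjusted p = 0.00235, adjusted p = 0.338 with an estimated correlation). In the ribosome list 2 of 29 fell (adjusted p = 0.000189, adjusted p = 0.4997 with an estimated correlation).

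In the list of NuB4 genes 1 of 4 fell in nasp, and 3 when adjusted over the list alone (adjusted p = 0.000493, adjusted p = 0.103 with an estimated correlation). The gene that fell over all genes tested was the mutated NASP, so the genotype largely set this call. Of 19 glucosinolate genes 0 changed (median -0.06, adjusted p = 0.0228, adjusted p = 0.516 with an estimated correlation), and the call ended without wild type replicate 3 (adjusted p = 0.0998) or nasp replicate 1 (adjusted p = 0.727). Of 3 measured genes of the list silenced by DNA methylation or heterochromatin, QQS rose by 0.94 ± 0.14 (list adjusted p = 0.0281, adjusted p = 0.142 with an estimated correlation), and the call ended without wild type replicate 2 (adjusted p = 0.0552) or 3 (adjusted p = 0.0803) or nasp replicate 2 (adjusted p = 0.0675). With voom weights, 545 genes rose and 593 fell in nasp, so which direction held more genes turned. The median change over all genes was -0.045 in that fit, which also divides each library by its total. Scaling and weights were not parted. Without wild type replicate 2 the count of 945 changed genes was 612, and without nasp replicate 2 it was 519.

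Seedlings of hag2 nasp and of msi2 msi3 nasp differed from the wild type in most of the genes tested. In hag2 nasp 16117 of 24305 genes changed (66.3%; 8051 rose and 8066 fell, 2864 and 3455 at least 2-fold) and in msi2 msi3 nasp 16242 (66.8%; 8160 rose and 8082 fell, 2900 and 3458 at least 2-fold). With voom weights 8233 rose and 7828 fell in hag2 nasp, so which direction held more genes turned there, as it did without the filter (8122 and 8066) and without wild type replicate 1 (7693 and 7640). In msi2 msi3 nasp it turned without msi2 msi3 nasp replicate 1 (7704 and 7713) or 3 (7693 and 7699). NATA1, an N-acetyltransferase of defence, went from 43.0 ± 42.0 in the wild type to 10264 ± 2205 in hag2 nasp, a rise of 8.34 ± 0.49 (log2, adjusted p = 5.93e-11). ELI3-2, an alcohol dehydrogenase, rose by 8.05 ± 0.63 and 8.01 ± 0.63 in hag2 nasp and msi2 msi3 nasp, the defence gene PR1 by 7.72 ± 0.42 and 8.71 ± 0.42, and CYP82G1, which makes volatile homoterpenes, by 7.04 ± 0.58 and 6.93 ± 0.58. The expansin gene EXPA8 went from 2883 ± 389 to 30.1 ± 14.8 in hag2 nasp, and the kinase gene CIPK20 from 552 ± 109 to 4.88 ± 1.90. AT3G46370, a leucine-rich repeat kinase gene, fell by 7.02 on the log2 scale in both. In msi2 msi3 nasp AT2G24255 stood at 121 ± 5.73 and was listed at 0 in the wild type. AT1G68250, also listed at 0 there, stood at 55.1, 661 and 109.7 in the msi2 msi3 nasp libraries, so replicate 2 carries its mean of 275 ± 335.

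DNA damage response genes rose in both nasp combinations, 15 of 15 in hag2 nasp (median 1.91, adjusted p = 2.81e-09) and 14 of 15 in msi2 msi3 nasp (median 1.96, adjusted p = 8.22e-09). Of the lists called in these groups, 18 and 17, only this one held with an estimated correlation in each. SMR7, an inhibitor of cyclin-dependent kinases, rose by 5.35 ± 0.19 and 5.06 ± 0.19, PARP2 by 2.81 ± 0.08 and 2.59 ± 0.08, and XRI1 by 2.78 ± 0.08 and 2.60 ± 0.08. All 37 photosynthesis genes fell in both, with medians of -1.48 in hag2 nasp (adjusted p = 7.05e-18, adjusted p = 0.199 with an estimated correlation) and -1.39 in msi2 msi3 nasp (adjusted p = 6.44e-17, adjusted p = 0.215 with an estimated correlation). LHCB1.1 went from 19387 ± 3413 to 1446 ± 88.8 in hag2 nasp, and LHCB2.3 changed by -4.79 ± 0.16 and -4.73 ± 0.16. Counts adjusted over the list alone were the same for all called lists but the unfolded protein response in hag2 nasp and the iron, senescence and auxin and cytokinin lists in msi2 msi3 nasp, where they were 8 risen, 17 fallen, 10 risen and 10 fallen.

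Defence and pigment genes were higher in both. Of 27 salicylic acid and immune genes, 24 rose and 1 fell in hag2 nasp (median 2.04, adjusted p = 6.44e-09, adjusted p = 0.178 with an estimated correlation), and 25 rose and 1 fell in msi2 msi3 nasp (median 2.58, adjusted p = 2.77e-11, adjusted p = 0.110 with an estimated correlation). The regulator SARD1 rose by 4.04 ± 0.17 and 4.69 ± 0.17. Of 19 jasmonate genes, 19 rose in hag2 nasp (adjusted p = 4.33e-07, adjusted p = 0.199 with an estimated correlation) and 17 in msi2 msi3 nasp (adjusted p = 2.55e-05, adjusted p = 0.262 with an estimated correlation). The lipoxygenase gene LOX3 rose by 3.22 ± 0.15 and 3.06 ± 0.15. Of 13 anthocyanin and flavonoid genes, 12 rose in hag2 nasp (adjusted p = 0.000449, adjusted p = 0.349 with an estimated correlation) and 12 in msi2 msi3 nasp (adjusted p = 0.000148, adjusted p = 0.284 with an estimated correlation). The regulator TT8 changed by 2.34 ± 0.24 and 2.80 ± 0.24. Of 11 senescence genes, 10 and 9 rose (adjusted p = 0.000158 and 0.000123, adjusted p = 0.199 and 0.215 with an estimated correlation). SAG13 changed by 5.66 ± 0.36 in hag2 nasp. Of 10 touch and wound genes, 7 and 9 rose (adjusted p = 0.00326 and 0.000206, adjusted p = 0.349 and 0.262 with an estimated correlation). TCH3 changed by 2.94 ± 0.14 in hag2 nasp.

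Heat shock, protein folding, ribosome and seed genes were also higher. Of 15 heat shock genes, 11 rose and 1 fell in hag2 nasp and 12 rose and 1 fell in msi2 msi3 nasp (adjusted p = 0.0362 and 0.00243, adjusted p = 0.250 and 0.191 with an estimated correlation). HSP90.1 changed by 1.73 ± 0.09 and 2.43 ± 0.09. Of 9 unfolded protein response genes, 7 and 8 rose (adjusted p = 0.00464 and 0.00118, adjusted p = 0.295 and 0.262 with an estimated correlation). The luminal chaperone BIP3 changed by 4.67 ± 0.38 and 5.21 ± 0.38. In the ribosome list 22 of 29 rose and 1 fell in hag2 nasp, and 24 rose in msi2 msi3 nasp (adjusted p = 0.000158 and 3.42e-06, adjusted p = 0.404 and 0.284 with an estimated correlation). In the seed maturation list 10 of 13 rose and 1 fell in hag2 nasp, and 10 rose in msi2 msi3 nasp (adjusted p = 0.0413 and 0.0209, adjusted p = 0.423 and 0.344 with an estimated correlation). The storage albumin gene SESA1 rose by 5.85 ± 0.42 and 5.93 ± 0.42. Of 17 abscisic acid genes 13 rose and 2 fell in msi2 msi3 nasp (adjusted p = 0.00519, adjusted p = 0.453 with an estimated correlation). RD22 changed by 1.94 ± 0.10.

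Iron deficiency, root and growth hormone genes were lower in both. Of 18 iron deficiency genes 16 fell and 1 rose in each, with medians of -3.26 and -3.89 (adjusted p = 4.04e-05 and 1.54e-05, adjusted p = 0.224 and 0.234 with an estimated correlation). The ferric reductase gene FRO2 changed by -4.91 ± 0.26 and -5.19 ± 0.26, and the regulator BHLH38 went from 143 ± 10.1 in the wild type to 0.668 ± 1.16 in hag2 nasp. Of the 13 root markers, which stood in for organ makeup, 11 fell and 2 rose in each (adjusted p = 0.00243 and 0.000252, adjusted p = 0.199 and 0.191 with an estimated correlation). CASP1 of the endodermis changed by -2.07 ± 0.12 and -2.47 ± 0.12. Of 12 auxin and cytokinin response genes, 10 and 8 fell and 1 rose in each (adjusted p = 0.00805 and 0.00519, adjusted p = 0.178 and 0.149 with an estimated correlation). IAA29 changed by -4.20 ± 0.32 and -4.24 ± 0.32. In hag2 nasp 8 of 10 cold genes fell and 1 rose (adjusted p = 0.0237, adjusted p = 0.423 with an estimated correlation). KIN2 changed by -2.12 ± 0.18 and ZAT12 by 1.90 ± 0.18. Also in hag2 nasp, 5 of 8 morning clock genes fell (adjusted p = 0.0413, adjusted p = 0.224 with an estimated correlation) and 7 of 8 evening clock genes fell (adjusted p = 0.00616, adjusted p = 0.199 with an estimated correlation). In msi2 msi3 nasp 12 of 15 phosphate starvation genes fell and 2 rose (median -1.79, adjusted p = 0.000206, adjusted p = 0.284 with an estimated correlation). The noncoding RNA AT4 changed by -4.96 ± 0.18. In hag2 nasp the heat shock call ended without wild type replicate 2 (adjusted p = 0.0514) and the morning clock call without hag2 nasp replicate 2 (adjusted p = 0.0540). The seed maturation call there ended without wild type replicate 3 (adjusted p = 0.0972), hag2 nasp replicate 1 (adjusted p = 0.0868) or hag2 nasp replicate 2 (adjusted p = 0.0648).

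Set against nasp, to ask what loss of HAG2 or of MSI2 and MSI3 adds where NASP is lowered, DNA damage response genes rose and photosynthesis genes fell. PARP2 rose by 2.66 ± 0.08 in hag2 nasp (adjusted p = 9.42e-15), and the DNA repair gene GMI1 rose by 3.82 ± 0.14 in hag2 nasp and 3.84 ± 0.14 in msi2 msi3 nasp. LHCB1.1, which rose in nasp, stood at 49708 ± 4172 in nasp and 1446 ± 88.8 in hag2 nasp. The clock genes CCA1 and LNK2 changed by -3.76 ± 0.19 and -3.02 ± 0.09 in hag2 nasp against nasp. Against nasp, 16226 genes changed in hag2 nasp (8136 rose and 8090 fell, 2873 and 3532 at least 2-fold) and 16269 in msi2 msi3 nasp (8175 rose and 8094 fell, 2915 and 3522 at least 2-fold). With voom weights 8845 rose and 7324 fell in hag2 nasp and 8928 and 7364 in msi2 msi3 nasp. Which direction held more genes turned in both with median-ratio scaling (8094 and 8104, 8122 and 8126) and with at least 1 CPM in 3 libraries (7466 and 7474, 7451 and 7465), and in msi2 msi3 nasp without its replicate 3 (7704 and 7771). DNA damage response genes rose, 15 of 15 in hag2 nasp (adjusted p = 8.67e-09) and 14 of 15 in msi2 msi3 nasp (adjusted p = 2.15e-08), with the same counts when adjusted over the list alone, and these calls held with an estimated correlation. All 37 photosynthesis genes fell in both (adjusted p = 1.82e-19 and 1.40e-18, adjusted p = 0.206 and 0.207 with an estimated correlation). Of the 17 histone genes 15 rose and 1 fell in both, with a median of 1.15 in hag2 nasp (adjusted p = 7.04e-06 and 4.26e-06, adjusted p = 0.259 and 0.251 with an estimated correlation). In hag2 nasp 7 of 8 morning clock genes fell (adjusted p = 0.00367, adjusted p = 0.162 with an estimated correlation). The tests called 16 lists in hag2 nasp and 17 in msi2 msi3 nasp; all but DNA damage lost the call, with adjusted p from 0.162 to 0.474 and from 0.122 to 0.499 with an estimated correlation. The cold response call in hag2 nasp, 7 fallen and 1 risen of 10, and 8 fallen and 1 risen when adjusted over the list alone (adjusted p = 0.0287, adjusted p = 0.474 with an estimated correlation), ended without nasp replicate 3 (adjusted p = 0.0525).

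In the 12-day libraries labelled hag2 msi2 msi3, 5 of 8 morning clock genes fell and 4 of 15 DNA damage response genes rose. The defensin genes PDF1.2c and PDF1.2A rose by 3.96 ± 0.48 and 3.15 ± 0.30 (adjusted p = 8.89e-05 and 7.95e-06), PDF1.2A from 28.0 ± 11.4 to 248 ± 76.6. At 20 days they changed by -6.30 and -4.42 on the log2 scale (adjusted p = 0.00265 and 0.00734), PDF1.2c from 746 ± 749 and PDF1.2A from 904 ± 874, with a difference between ages of -10.26 ± 1.44 and -7.56 ± 1.18 (adjusted p = 0.00330 and 0.00626). Wild type libraries at 20 days spread from 22.2 to 1518 for PDF1.2c, and from 54.0 to 1799 for PDF1.2A. For PDF1.2c (AT5G44430), hag2 msi2 msi3 against wild type, 20 days, the call ended with robust empirical Bayes (adjusted p = 0.0744) and with voom weights (adjusted p = 0.476). For PDF1.2A (AT5G44420), hag2 msi2 msi3 against wild type, 20 days, it ended with both as well (adjusted p = 0.134 and 0.341), and so did the calls of a difference between ages. BSU1, a phosphatase of brassinosteroid signalling, rose by 3.42 ± 0.35, GRP19, of the pollen coat, by 3.06 ± 0.41, PCR1 by 2.61 ± 0.41 and AT5G15360 by 5.04 ± 0.57. CCA1 went from 351 ± 122 to 43.1 ± 5.34, a change of -2.94 ± 0.19. AT2G08735, AT3G05945 and AT3G06955 changed by -2.99 ± 0.49, -2.78 ± 0.26 and -2.77 ± 0.44. In all 982 genes changed, of which 505 rose and 477 fell, and 78 and 80 of these did so at least 2-fold. With voom weights 462 rose and 566 fell, so which direction held more genes turned, as it did without any of the 6 libraries but wild type replicate 2.

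Of the 8 morning clock genes 5 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone (median -0.80, adjusted p = 4.11e-09). PRR9 changed by -2.13 ± 0.18 and LNK2 by -0.98 ± 0.09. As in nasp, an effect of the hour of harvest on these clock genes cannot be told apart from that of genotype. Of 15 DNA damage response genes 4 rose, and 5 when adjusted over the list alone (median 0.23, adjusted p = 6.99e-05). GMI1 rose by 1.19 ± 0.14, the ribonucleotide reductase gene TSO2 by 0.41 ± 0.06 and CYCB1;1 by 0.46 ± 0.10. Of the NuB4 genes 2 of 4, the mutated HAG2 and MSI3, fell, also when adjusted over the list alone (adjusted p = 4.43e-06), a call that the genotype set. These 3 calls and that of the histone list held with an estimated correlation; 8 others did not. Of 10 cold genes 5 fell, and 6 when adjusted over the list alone (median -0.82, adjusted p = 3.01e-07, adjusted p = 0.159 with an estimated correlation). GOLS3 changed by -1.24 ± 0.18 and KIN1 by -1.18 ± 0.21. Of 37 photosynthesis genes 3 rose and 5 fell, and 3 rose and 7 fell when adjusted over the list alone (adjusted p = 0.00472, adjusted p = 0.675 with an estimated correlation). LHCB2.1, LHCB2.2 and LHCB2.3 changed by -0.92 ± 0.09, -0.97 ± 0.10 and -1.34 ± 0.16. Of 27 salicylic acid genes 5 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone (adjusted p = 0.000330, adjusted p = 0.306 with an estimated correlation). SARD1 changed by 0.99 ± 0.17. Of 21 replication and cell cycle genes 2 rose, and 6 when adjusted over the list alone (adjusted p = 3.01e-07, adjusted p = 0.0595 with an estimated correlation). CYCB1;2 changed by 0.51 ± 0.10. In the ribosome list 4 of 29 rose, and 18 when adjusted over the list alone (adjusted p = 7.02e-11, adjusted p = 0.253 with an estimated correlation). Of 15 phosphate starvation genes 1 fell, and 6 when adjusted over the list alone (adjusted p = 5.93e-06, adjusted p = 0.306 with an estimated correlation). Of 17 abscisic acid genes 2 fell, and 3 when adjusted over the list alone (adjusted p = 0.00292, adjusted p = 0.570 with an estimated correlation). Of 19 glucosinolate genes 1 rose, and 2 when adjusted over the list alone (adjusted p = 0.0258, adjusted p = 0.570 with an estimated correlation). The abscisic acid call ended without wild type replicate 2 (adjusted p = 0.132), and the glucosinolate call without wild type replicate 1 (adjusted p = 0.0603), wild type replicate 2 (adjusted p = 0.0677) or hag2 msi2 msi3 replicate 3 (adjusted p = 0.260). The count of 982 fell to 441 and 599 without wild type replicates 2 and 3, and to 454, 538 and 598 without hag2 msi2 msi3 replicates 1, 2 and 3.

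At 20 days, flower and anther genes were higher in msi2 msi3 and in the libraries labelled hag2 msi2 msi3 than in the wild type. MS2, needed for the pollen wall, went from 34.6 ± 18.1 in the wild type to 711 ± 172 in msi2 msi3 and 442 ± 57.0 in hag2 msi2 msi3. The tapetum genes A7, ATA27 and LTP12 stood at 152, 127 and 105 in msi2 msi3 and at 148, 262 and 121 in hag2 msi2 msi3, and lay at the rounding floor of the table, taken as 0, in the wild type, as did AT5G13380 (131 and 107) and, in hag2 msi2 msi3, TSM1 (121). The floral organ identity genes SEP2 and PI rose by 1.67 ± 0.15 and 1.26 ± 0.15, and by 1.56 ± 0.16 and 1.15 ± 0.16 (log2). SEP3 went from 197 ± 41.2 to 480 ± 33.2 in msi2 msi3 and 393 ± 40.9 in hag2 msi2 msi3. AT1G47980 stood at 327 ± 60.2 and 246 ± 23.2, against 5.94 ± 10.1 in the wild type.

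Of the 19 floral integrator and flower identity genes, 10 rose in msi2 msi3 (median 0.68, adjusted p = 2.16e-10) and 8 in hag2 msi2 msi3 (median 0.65, adjusted p = 3.92e-09), and 11 and 12 when adjusted over the list alone. Of the 7 anther and pollen markers, which stood in for organ makeup, 3 rose in each (adjusted p = 3.14e-06 and 2.18e-07), and 4 in each when adjusted over the list alone; A9 rose by 3.35 ± 0.36 and 2.84 ± 0.36 and the regulator AMS by 2.05 ± 0.25 and 1.60 ± 0.25. Cold genes fell, 8 of 10 in msi2 msi3 (median -1.03, adjusted p = 1.94e-10) and 5 of 10 in hag2 msi2 msi3 (median -0.75, adjusted p = 8.48e-08). Adjusted over the list alone, 9 fell in msi2 msi3, and 6 fell and 1 rose in hag2 msi2 msi3. COR15A changed by -0.96 ± 0.09 and -0.81 ± 0.09, COR15B by -1.07 ± 0.11 and -1.05 ± 0.11, and KIN2 by -0.99 ± 0.12 and -1.03 ± 0.12. Of 19 glucosinolate genes 9 fell and 1 rose in msi2 msi3 and 4 fell in hag2 msi2 msi3 (adjusted p = 6.88e-10 and 1.51e-07). Adjusted over the list alone, 13 fell and 1 rose, and 10 fell. MYB51 changed by -0.63 ± 0.09, BCAT4 by -0.45 ± 0.07 and CYP79F1 by -0.45 ± 0.07 in msi2 msi3, and MYB29 by -0.42 ± 0.08 in hag2 msi2 msi3. In the ribosome list 6 and 4 of 29 rose (adjusted p = 2.42e-07 and 8.48e-08), and 12 and 13 when adjusted over the list alone, with the fibrillarin gene FIB1 at 0.34 ± 0.06 in msi2 msi3. The floral, anther, cold, glucosinolate, ribosome and histone calls held in both mutants with an estimated correlation, as did the fall of 2 of 4 NuB4 genes in hag2 msi2 msi3 (3 when adjusted over the list alone, adjusted p = 2.69e-07). These 2 NuB4 genes are the mutated HAG2 and MSI3, so the genotype set this fall.

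**Figure D3:**
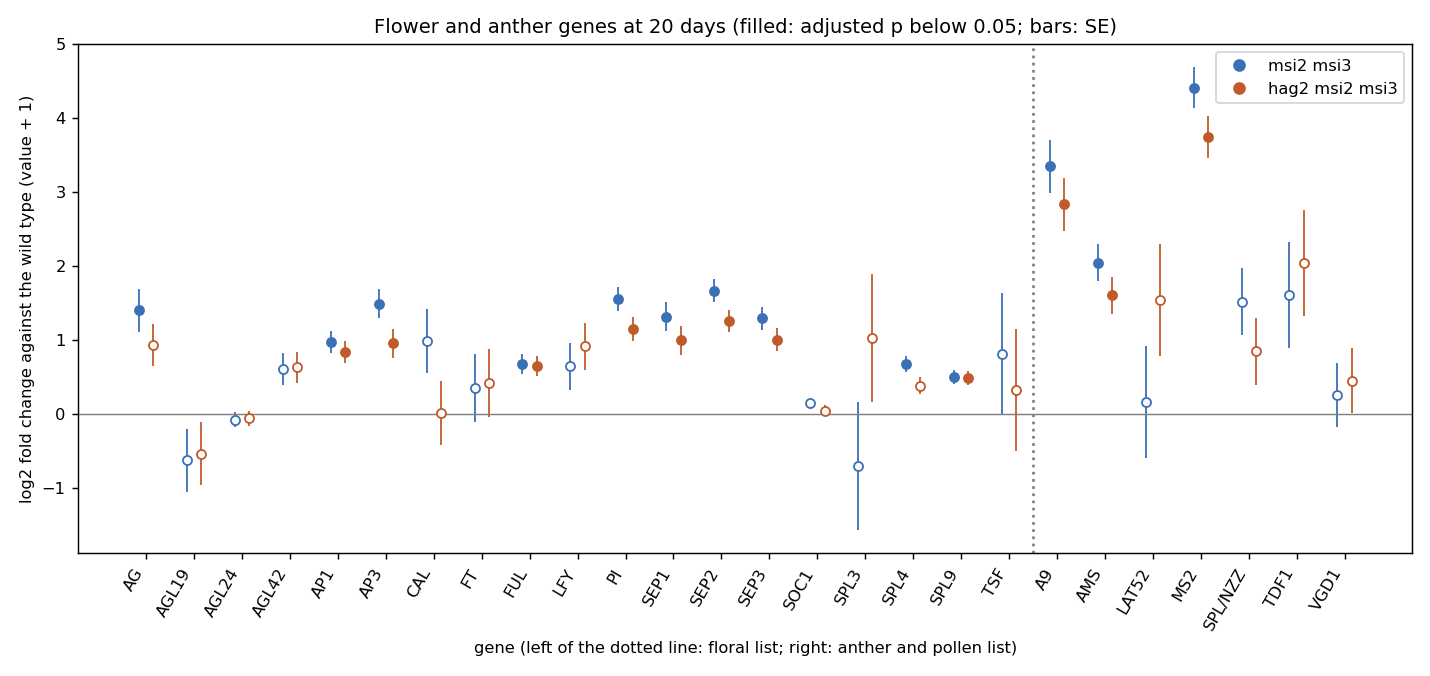
Log2 fold change against the wild type at 20 days (y axis) of the floral integrator and flower identity genes and the anther and pollen markers, in msi2 msi3 (blue) and hag2 msi2 msi3 (orange), with the standard error of the fit; filled points have an adjusted p below 0.05. MS2 stands highest among the named genes, at 4.41 in msi2 msi3 and 3.75 in hag2 msi2 msi3.

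In msi2 msi3 1802 of 23707 genes changed (819 rose and 983 fell, 346 and 137 at least 2-fold) and in hag2 msi2 msi3 1017 (612 rose and 405 fell, 231 and 71 at least 2-fold). AT3G01345 went from 141 ± 121 in the wild type to 20356 ± 2613 in msi2 msi3, a rise of 7.71 ± 0.54. AT2G01422 fell by 7.36 on the log2 scale in msi2 msi3 and fell by 7.49 in hag2 msi2 msi3, AT2G13550 changed by -3.06 ± 0.30 in hag2 msi2 msi3, and CYP71A13, of camalexin synthesis, by -3.32 ± 0.46 in msi2 msi3; AT1G75945 (246 in the wild type) and AT1G64795 (103) lay at the rounding floor in msi2 msi3. With voom weights 984 genes rose and 754 fell in msi2 msi3, and 497 rose and 508 fell in hag2 msi2 msi3, so which direction held more genes turned in both, and in msi2 msi3 it turned without wild type replicate 2 as well (563 and 545). Without 1 library the count for msi2 msi3 was 1078, 1108 and 1188 (wild type replicates 1, 2 and 3) and 1137 and 1193 (msi2 msi3 replicates 2 and 3), and that for hag2 msi2 msi3 was 662, 656 and 626 (wild type replicates 1, 2 and 3) and 571 (hag2 msi2 msi3 replicate 3).

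Other lists were called in msi2 msi3 without holding under an estimated correlation. Of 27 salicylic acid genes 1 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.000865, adjusted p = 0.230 with an estimated correlation). CBP60G changed by -1.46 ± 0.18 and WRKY70 by -0.87 ± 0.09. Of 10 touch and wound genes 1 rose and 5 fell, and 6 fell when adjusted over the list alone (adjusted p = 0.000270, adjusted p = 0.160 with an estimated correlation). WRKY33 changed by -0.97 ± 0.12. Of 12 anthocyanin genes 3 rose, and 5 when adjusted over the list alone (adjusted p = 0.00480, adjusted p = 0.0838 with an estimated correlation). The chalcone synthase gene CHS changed by 1.04 ± 0.10. Of 8 evening clock genes 3 rose, and 4 when adjusted over the list alone (adjusted p = 0.00755, adjusted p = 0.0838 with an estimated correlation). PRR5 changed by 0.37 ± 0.06. Of the NuB4 genes 2 fell, the mutated MSI2 and MSI3, and 2 fell and 1 rose when adjusted over the list alone (adjusted p = 0.00895, adjusted p = 0.0838 with an estimated correlation). Of 17 abscisic acid genes 1 rose and 6 fell, and 8 fell when adjusted over the list alone (adjusted p = 0.0109, adjusted p = 0.144 with an estimated correlation). RAB18 changed by -0.62 ± 0.12. In the unfolded protein response list 2 of 9 fell, and 4 when adjusted over the list alone (adjusted p = 0.000458, adjusted p = 0.160 with an estimated correlation). Of 37 photosynthesis genes 2 fell (adjusted p = 0.000401, adjusted p = 0.230 with an estimated correlation). Of 19 jasmonate genes 2 rose and 5 fell, and 3 rose and 9 fell when adjusted over the list alone (adjusted p = 0.0274, adjusted p = 0.402 with an estimated correlation). AOC2 changed by -0.63 ± 0.07; of 17 iron deficiency genes 2 fell (adjusted p = 0.0364, adjusted p = 0.188 with an estimated correlation). And of 15 phosphate starvation genes 4 fell, and 2 rose and 4 fell when adjusted over the list alone (adjusted p = 0.0109, adjusted p = 0.160 with an estimated correlation). Without wild type replicate 2 the jasmonate, iron and phosphate calls ended (adjusted p = 0.234, 0.143 and 0.0703), without wild type replicate 3 the iron call (adjusted p = 0.0581), and without msi2 msi3 replicate 2 the jasmonate and iron calls (adjusted p = 0.0518 and 0.0989).

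In hag2 msi2 msi3 at 20 days, 4 of 10 touch and wound genes rose, and 7 when adjusted over the list alone (adjusted p = 7.17e-06, adjusted p = 0.110 with an estimated correlation). The calmodulin-like gene TCH3 changed by 0.82 ± 0.12 and CMPG1 by 1.16 ± 0.18. Of 17 iron deficiency genes 2 fell, and 5 when adjusted over the list alone (adjusted p = 0.000469, adjusted p = 0.0586 with an estimated correlation). The regulator BHLH101 changed by -2.11 ± 0.40. Of 19 jasmonate genes 4 fell, and 2 rose and 9 fell when adjusted over the list alone (adjusted p = 0.0371, adjusted p = 0.582 with an estimated correlation). AOC2 changed by -0.43 ± 0.07. The jasmonate call ended without wild type replicate 2 (adjusted p = 0.359), wild type replicate 3 (adjusted p = 0.0530), or hag2 msi2 msi3 replicate 1 (adjusted p = 0.0599) or 3 (adjusted p = 0.0513).

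Touch and wound genes were also higher when the 20-day hag2 msi2 msi3 libraries were set against msi2 msi3. These groups differ in MSI2 as well as in HAG2, so the comparison does not isolate the hag2 mutation. The labels do not say whether groups were harvested separately. An effect of handling on touch and wound genes cannot be told apart from that of genotype in any comparison. Of the 10 genes 9 rose in hag2 msi2 msi3 against msi2 msi3, and 10 when adjusted over the list alone (adjusted p = 6.78e-20), a call that held with an estimated correlation. TCH4, a cell wall enzyme, went from 3302 ± 599 to 10355 ± 847, a rise of 1.66 ± 0.14 (adjusted p = 2.95e-05), ZAT10 rose by 1.42 ± 0.21 and WRKY40 by 1.47 ± 0.23. AT1G75945 and AT1G64795 stood at 74.3 and 32.8 and lay at the rounding floor in msi2 msi3. Of 27 salicylic acid genes 3 rose, and 3 rose and 1 fell when adjusted over the list alone (adjusted p = 0.0205, adjusted p = 0.409 with an estimated correlation), namely PR5 by 1.02 ± 0.12, CBP60G by 1.13 ± 0.18 and WRKY53 by 0.94 ± 0.17. Of the 17 histone genes 1 fell, and 3 when adjusted over the list alone (median -0.15, adjusted p = 8.42e-06, adjusted p = 0.280 with an estimated correlation). MYB51 rose by 0.59 ± 0.09 and MYB34 fell by 0.67 on the log2 scale, in a glucosinolate list in which 1 rose and 1 fell of 19, and 4 rose and 2 fell when adjusted over the list alone (adjusted p = 0.0205, adjusted p = 0.280 with an estimated correlation). Called upward were also the photosynthesis list, with 1 of 37 risen (adjusted p = 0.000319), the unfolded protein response, with 0 of 9, and 2 when adjusted over the list alone (adjusted p = 0.00259), phosphate starvation, with 1 of 15 (adjusted p = 0.0210), and cold, with 0 of 10 (adjusted p = 0.0210), each at adjusted p = 0.280 with an estimated correlation. Called downward were the evening clock, with 1 of 8 fallen, and 3 when adjusted over the list alone (adjusted p = 0.00259, adjusted p = 0.146 with an estimated correlation). So were the anthocyanin list, with 0 of 12, and 1 when adjusted over the list alone (adjusted p = 0.0205), the floral list, with 0 of 19 (adjusted p below 0.05), and auxin and cytokinin, with 1 of 12, and 2 when adjusted over the list alone (adjusted p = 0.0484), each at adjusted p = 0.280 with an estimated correlation. The markers that stood in for organ makeup were not called, with 1 of 11 root markers risen, and 2 when adjusted over the list alone (median 0.44, adjusted p = 0.159), and 0 of 7 anther and pollen markers changed (median -0.44, adjusted p = 0.389). A difference in organ makeup is not excluded by this. Leaving out any of the 6 libraries ended the call of at least 1 of 8 lists, at adjusted p up to 0.5003. In all 281 genes changed (242 rose and 39 fell, 43 and 9 at least 2-fold; 142 and 91 with voom weights), and the count was 104 without hag2 msi2 msi3 replicate 3, 176, 114 and 136 without msi2 msi3 replicates 1, 2 and 3, and 177 with only these groups in the fit.

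The libraries labelled hag2 msi2 msi3 were compared between ages by a test of the difference itself. The change of LHCB2.3 was -1.34 ± 0.16 at 12 days and -0.01 ± 0.06 at 20 days (difference 1.33 ± 0.16, adjusted p = 0.00157), and LHCB2.1 differed by 0.98 ± 0.12. LNK2 changed by -0.98 ± 0.09 at 12 days and by 0.02 ± 0.12 at 20 days, and this difference passed the test. WRKY54, of the salicylic acid list, differed by -1.43 ± 0.25, and RHS14, a root hair gene, by 5.17 ± 0.60. RHS14 stood at 150 in the wild type and 129 in the mutant at 12 days, and at 2.04 and 78.0 at 20 days. Unequal root tissue in the 20-day libraries is not excluded as a source of this difference. In all 179 of 21893 genes differed, 122 upward and 57 downward from 12 to 20 days, 58 and 17 at least 2-fold. Age was confounded with sequencing platform, read length and growth on plates or in a chamber, so these cannot be told apart, and the count was 92 and 95 without wild type replicates 2 and 3 at 12 days, 104 and 117 without hag2 msi2 msi3 replicates 2 and 3 at 12 days, 114 and 101 without wild type replicates 2 and 3 at 20 days, and 302 and 75 without hag2 msi2 msi3 replicates 1 and 3 at 20 days.

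Genes called in more than 1 mutant group were counted by direction. Of the genes called in both nasp combinations, 7232 rose and 7264 fell in both and 26 went opposite ways, against 2703, 2682 and 5385 expected if calls were independent. PR1 rose and AT3G46370 fell in both. For msi2 msi3 and hag2 msi2 msi3 at 20 days 389 rose and 288 fell in both (21.1 and 16.8 expected) and 8 went opposite ways (39.4 expected). For nasp and hag2 nasp, 236 rose and 152 fell in both (201 and 112 expected) and 407 went opposite ways (313 expected), LHCB1.1 and CCA1 among them. For nasp and msi2 msi3 nasp, 257 rose and 147 fell in both (204 and 112 expected) and 385 went opposite ways (315 expected). For nasp and hag2 msi2 msi3 at 12 days 90 rose and 32 fell in both (12.6 and 6.61 expected) and 126 went opposite ways (18.9 expected), CCA1 and LNK2 among them. For hag2 msi2 msi3 at 12 days and hag2 nasp, 272 rose and 265 fell in both (167 and 158 expected) and 297 went opposite ways (326 expected). With msi2 msi3 nasp, 284 rose and 283 fell in both (169.5 and 159 expected) and 277 went opposite ways (328 expected). Between the ages, with separate wild types, 88 genes rose and 115 fell in hag2 msi2 msi3 at both (11.9 and 8.41 expected) and 8 went opposite ways (20.1 expected). Across all genes the changes correlated at 0.124 between nasp and either nasp combination, 0.387 between nasp and hag2 msi2 msi3, 0.262 and 0.284 between hag2 msi2 msi3 and the nasp combinations, 0.954 between these 2, and 0.697 between the mutants at 20 days. Unchanged groups simulated against the same controls gave correlations of 0.497 to 0.4995. The covariances were, in the same order, 0.0495 and 0.0509, 0.0452, 0.107 and 0.119, 1.37, and 0.242, against 0.0367 to 0.0370 simulated at 12 days and 0.0787 at 20 days. The 3 control libraries cannot be split, so part of the overlap within an age may come from the wild type libraries that the comparisons share.

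**Figure D4:**
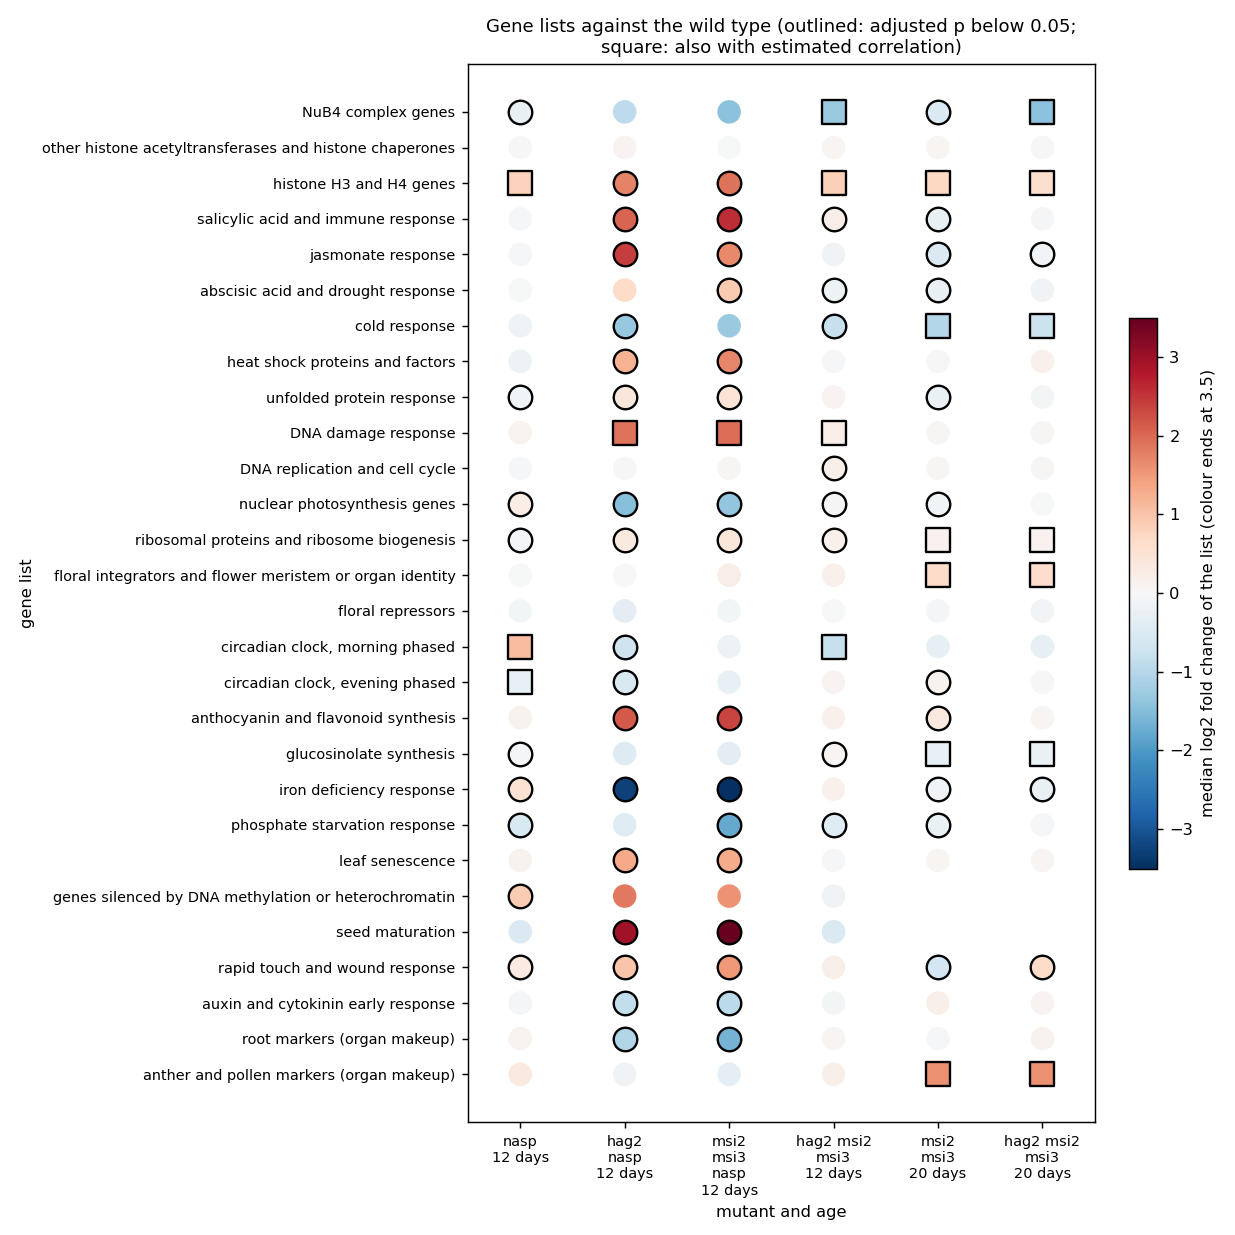
Median log2 fold change (colour) of the 28 gene lists in the 6 comparisons with a wild type; outlined cells have an adjusted p below 0.05 and squares mark calls that held with an estimated correlation. The histone H3 and H4 list is outlined in all 6 columns, and cells are empty at 20 days for the lists not tested.

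The lists of other histone acetyltransferases and chaperones and of floral repressors were not called in any of these comparisons. Of the 19 acetyltransferase and chaperone genes, 8 rose and 6 fell in each nasp combination, 1 rose in hag2 msi2 msi3 at 12 days, and 0 changed in nasp and in both mutants at 20 days; the list's median lay so close to 0 that its sign turned with voom weights in nasp, msi2 msi3 nasp and hag2 msi2 msi3 at 20 days. Of the 12 floral repressors, 4 rose and 6 fell in hag2 nasp, 4 rose and 4 fell in msi2 msi3 nasp, 2 rose in nasp, 1 fell in hag2 msi2 msi3 at 12 days, 3 fell in msi2 msi3, and 2 rose and 1 fell in hag2 msi2 msi3 at 20 days.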

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

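The count of splits in this part was planned and its tally by kind of split was chosen after the result was seen. The change in the libraries labelled hag2 msi2 msi3 differed between 12 and 20 days for 179 of 21893 genes by a test of the difference itself, with RHS14 and LHCB2.3 among them. The lists whose difference passed were histone H3 and H4 genes (adjusted p = 4.41e-05, adjusted p = 0.282 with an estimated correlation, median -0.24), DNA replication and cell cycle (adjusted p = 1.81e-05, adjusted p = 0.111 with an estimated correlation, median -0.18), and salicylic acid and immune response (adjusted p = 0.00230, adjusted p = 0.282 with an estimated correlation, median -0.20). DNA damage response (adjusted p = 0.0294, adjusted p = 0.299 with an estimated correlation), glucosinolate synthesis (adjusted p = 3.23e-09, adjusted p = 0.0906 with an estimated correlation) and iron deficiency response (adjusted p = 6.88e-07, adjusted p = 0.0668 with an estimated correlation) also differed downward. Upward differences were those of the morning clock (adjusted p = 6.72e-06, adjusted p = 0.0528 with an estimated correlation), anther and pollen markers (adjusted p = 1.81e-05, adjusted p = 0.0528 with an estimated correlation), floral genes (adjusted p = 0.0160, adjusted p = 0.0906 with an estimated correlation) and phosphate starvation genes (adjusted p = 0.00423, adjusted p = 0.479 with an estimated correlation). Touch and wound genes (adjusted p = 0.0161, adjusted p = 0.476 with an estimated correlation) and photosynthesis genes (adjusted p = 0.0367, adjusted p = 0.610 with an estimated correlation) differed upward as well, though the photosynthesis median was -0.00. Of all 12 lists, 0 held with an estimated correlation.

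The DNA damage, photosynthesis, phosphate and touch calls each ended without at least 1 library, at adjusted p up to 0.196. These libraries were wild type replicate 3 and hag2 msi2 msi3 replicates 1 and 2 at 12 days, and wild type replicates 1 and 3 and hag2 msi2 msi3 replicates 2 and 3 at 20 days. Of 100 splits of the libraries within each age, 4 gave at least 179 genes, the real one included, a share under 0.05. The other splits were drawn at random, so this share would vary with the draw. The highest other gave 2267, and this was the split that exchanged the genotypes at 20 days alone, which adds the changes of both ages and so follows the structure of the samples. Without it the highest were 276, 232 and 161 and the median was 0. The splits with 276 and 161 also exchanged all 6 libraries at 20 days, with 2 moved at 12 days, so they follow that structure in part, and that with 232 moved 4 at 20 days and 0 at 12 days. Splits that mix the genotypes within an age also break the genotype effect common to both ages and move it into the spread. Their low counts were thus largely fixed beforehand. The share cannot decide whether the difference between ages arose by chance, and no conclusion is drawn from it. Age, platform, read length and growth conditions cannot be told apart here.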

How the results depend on the processing

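Median-ratio scaling, robust empirical Bayes and voom weights were chosen after the results were seen. Since voom also divides each library by its total, a change under that setting can come from scaling or from weights. Count-based DESeq2 and edgeR fits were not run, because the deposited values are not counts. Replicate numbers did not pair the libraries (correlation across genes of -0.0557 to 0.0956 at 12 days and -0.0330 to 0.0524 at 20 days, genes not being independent replicates), and with them as a block each count of changed genes stayed within 1.5 times. The cause of the differences below was not tested.

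With an estimated correlation, 3 of 12 called lists held in nasp, 1 of 18 in hag2 nasp, 1 of 17 in msi2 msi3 nasp and 4 of 12 in hag2 msi2 msi3 at 12 days. The 4 include the NuB4 list, whose fall the genotype set. Against nasp, 1 of 16 held in hag2 nasp and 1 of 17 in msi2 msi3 nasp. At 20 days 6 of 17 held in msi2 msi3 and 1 of 12 in hag2 msi2 msi3 against msi2 msi3, and 0 of 12 in the difference between ages. With fry, 7 were called in nasp, 4 in hag2 msi2 msi3 against msi2 msi3 and 6 between ages. With only the compared groups in the fit, hag2 msi2 msi3 against msi2 msi3 gave 177 genes in place of 281.

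At an adjusted p below 0.01, calls shared in direction went from 388 to 179 for nasp and hag2 nasp, 404 to 179 for nasp and msi2 msi3 nasp, and 122 to 48 for nasp and hag2 msi2 msi3. With hag2 msi2 msi3 at 12 days they went from 537 to 179 for hag2 nasp and 567 to 195 for msi2 msi3 nasp. They went from 677 to 331 for the mutants at 20 days and from 203 to 75 for hag2 msi2 msi3 at both ages.

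Without 1 library the count ranged from 519 to 721 in nasp (945), 441 to 751 in hag2 msi2 msi3 at 12 days (982), 1078 to 1351 in msi2 msi3 (1802) and 571 to 1308 in hag2 msi2 msi3 at 20 days (1017). It ranged from 104 to 324 in hag2 msi2 msi3 against msi2 msi3 (281) and from 75 to 302 between ages (179).

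Changes that were not called and lay near 0 turned sign. For FWA (AT4G25530), nasp against wild type, 12 days, the change was 0.01, -0.0367 with voom weights and -0.334 to 0.339 without 1 library. For HAG2 (AT5G56740), nasp against wild type, 12 days, these were 0.01, -0.0307 and -0.0363 to 0.0750. For NASP (AT4G37210), hag2 msi2 msi3 against wild type, 20 days, they were 0.00, -0.0158 and -0.0363 to 0.0435. Without 1 library, MSI3 (AT4G35050), hag2 msi2 msi3 against msi2 msi3, 20 days, went from -0.07 to values of -0.248 to 0.0823. NASP (AT4G37210), hag2 nasp against nasp, 12 days, went from -0.18 to values of -0.319 to 0.0245. NASP (AT4G37210), msi2 msi3 nasp against nasp, 12 days, went from -0.11 to values of -0.253 to 0.0906.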

Other observations

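Some genes of the other histone types also rose, and no list test was run on them. HTB6, an H2B gene, rose in each comparison with a wild type, by 1.45 ± 0.11 in nasp (230 ± 8.59 against 83.9 ± 8.70), 3.74 ± 0.11 in hag2 nasp, 3.76 ± 0.11 in msi2 msi3 nasp, 2.04 ± 0.11 in hag2 msi2 msi3 at 12 days, and 1.87 ± 0.11 in msi2 msi3 at 20 days (log2), and it went from 293 ± 35.2 to 674 ± 73.8 in hag2 msi2 msi3 at 20 days. The H1 genes HON1 and HON2 also rose in each, by 0.55 ± 0.06 and 0.70 ± 0.06 in nasp. HTA11, which encodes the variant H2A.Z, fell by 0.96 on the log2 scale in hag2 nasp and by 0.90 in msi2 msi3 nasp, and HTA9 and HTA12 fell in both as well. Of 20 H2A and H2B genes, 12 rose in nasp, 16 rose and 3 fell in hag2 nasp, 17 rose and 3 fell in msi2 msi3 nasp, 14 rose in hag2 msi2 msi3 at 12 days, and 12 and 5 rose in msi2 msi3 and hag2 msi2 msi3 at 20 days. In nasp and msi2 msi3 8 of the 20 did not pass the test, and in hag2 msi2 msi3 6 did not at 12 days and 15 did not at 20 days.

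Set directly against each other, a comparison added after the results were seen, hag2 nasp and msi2 msi3 nasp differed in phosphate, immune and clock genes. PECP1, a phosphatase of phosphate starvation, stood at 73.4 ± 30.4 in hag2 nasp and 6.41 ± 4.37 in msi2 msi3 nasp, and AT5G20790 at 283 ± 59.2 and 29.7 ± 14.7. AT3G01345 stood at 32.0 and 3239, and BSU1 was lower in hag2 nasp by 3.91 on the log2 scale. Of 24305 genes 1539 differed, 746 higher and 793 lower in hag2 nasp. Phosphate starvation genes were higher in hag2 nasp, 12 of 15, and 13 when adjusted over the list alone (adjusted p = 3.05e-20). Salicylic acid genes were lower, 11 of 27, and 18 when adjusted over the list alone (adjusted p = 3.44e-12), as were morning clock genes, 5 of 8, and 7 when adjusted over the list alone (adjusted p = 9.07e-09). Root markers were higher, 6 of 13, and 8 when adjusted over the list alone (adjusted p = 4.24e-07). Lower in hag2 nasp were also 4 of 8 evening clock genes, and 5 when adjusted over the list alone (adjusted p = 6.73e-06), 4 of 15 heat shock genes, and 7 when adjusted over the list alone (adjusted p = 0.000229), and 3 of 12 floral repressors, and 4 when adjusted over the list alone (adjusted p = 0.000529). These 7 calls held with an estimated correlation, and of the 17 H3 and H4 genes 0 differed (adjusted p = 0.291).

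The 8 other lists called between hag2 nasp and msi2 msi3 nasp did not hold. Higher in hag2 nasp were 4 of 19 jasmonate genes, and 8 when adjusted over the list alone (adjusted p = 2.16e-06, adjusted p = 0.238 with an estimated correlation), and the DNA damage response list was called upward with 0 of 15 risen (adjusted p = 0.0396, adjusted p = 0.238 with an estimated correlation). Lower were 4 of 29 genes of the ribosome list, and 7 when adjusted over the list alone (adjusted p = 0.000102, adjusted p = 0.485 with an estimated correlation). Of 17 abscisic acid genes 2 were lower, and 3 when adjusted over the list alone (adjusted p = 0.000620, adjusted p = 0.485 with an estimated correlation). Of 10 touch and wound genes 2 were lower, and 5 when adjusted over the list alone (adjusted p = 0.000622, adjusted p = 0.399 with an estimated correlation). Of 37 photosynthesis genes 3 were lower, and 4 when adjusted over the list alone (adjusted p = 0.00431, adjusted p = 0.641 with an estimated correlation). The unfolded protein response list was called downward with 0 of 9 fallen (adjusted p = 0.0396, adjusted p = 0.491 with an estimated correlation). The anthocyanin list was called downward with 0 of 13 fallen, and 1 when adjusted over the list alone (adjusted p = 0.0484, adjusted p = 0.641 with an estimated correlation).

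In what follows, the tests of replicating cells, of 1 factor for each library, of reads moved between copies, of a few abundant genes, of root tissue and of flower buds were chosen after the results were seen. For the rise of H3 and H4 genes, a larger share of replicating cells is argued against as the whole cause. The replication list's median lay below 0.5 of the histone median in 6 of 6 comparisons, and the difference of the medians exceeded its standard error. That error was taken over the genes of each list, which are not independent, and not over libraries. This bound assumes that the list, which also holds other cell cycle genes, would rise at least 0.5 times as much. In hag2 msi2 msi3 at 12 days the replication list was itself called upward (median 0.21 against 0.83), so a part from replicating cells stays open there. Short genes or expression level are argued against too, since the histone median lay above the central 95% of 10000 matched random lists in 6 of 6. Reads moved between near-identical copies would leave the sum alone, and the smallest log2 change of the summed values was 0.630. A biological origin in the NuB4 mutations may account for the rise, a hypothesis found and tested on the same data.

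For the large response of hag2 nasp and msi2 msi3 nasp, 1 factor for each library is argued against as the whole cause. It would move all genes alike, and at least 2864 genes changed at least 2-fold in each direction in both. In these normalized values the median change over all genes was 0.00079 in hag2 nasp and -0.00071 in msi2 msi3 nasp. A shift of all genes beside these changes would therefore not be seen and stays open. The near-even counts of risen and fallen genes may come from the normalization. Median-ratio scaling left the lower count at 16113 and moved next to nothing, so it says nothing about scaling that differs between genes, which stays open. A few genes taking most of the values are argued against by the share of the 10 highest genes, which moved by at most 1.08 percentage points. Less root tissue alone would raise photosynthesis genes, yet 37 of 37 fell in each. Root markers fell as well, and photosynthesis genes can fall within an organ, so less root tissue beside other changes is not excluded. Also open is whether growth or stage differed between the plants, which the labels do not give.

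For the flower and anther genes at 20 days, 1 library with flowers is argued against, since without each mutant library in turn the floral list's adjusted p was at most 6.14e-07. Flower buds in the mutant samples cannot be told apart from higher expression in the same organs, with 3 of the 7 anther and pollen markers risen in each mutant, because the labels give no stage.

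The H2A and H2B median was at least 0.5 of the H3 and H4 median in 3 of 6 comparisons. Called genes were more frequent near the mutated loci at an adjusted p below 0.05 in 0 of 4 comparisons. Their share was higher there in 3 of 4, at 6% against 3.98% for hag2 msi2 msi3 at 12 days (adjusted p = 0.0800), 9% against 7.57% for msi2 msi3 and 4.83% against 4.27% for hag2 msi2 msi3 at 20 days. The bound set beforehand, 0 of 4, took a missed threshold as an exclusion, which was wrong given these shares. After the result was seen, sequence carried along with the mutations was therefore left open. The risen anther marker AMS was among the called genes near the loci in both 20-day comparisons, at 2.05 in msi2 msi3 and 1.60 in hag2 msi2 msi3 (log2), so this is open for AMS too.

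Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes. Every other split mixes both genotypes in each group and moves their difference into the spread. Low counts there were thus largely fixed beforehand, and no conclusion is drawn from them. The highest other split gave 1 gene for nasp (945) and hag2 msi2 msi3 at 12 days (982). It gave 0 for hag2 nasp (16117), msi2 msi3 nasp (16242), hag2 nasp and msi2 msi3 nasp against nasp (16226 and 16269), msi2 msi3 (1802), hag2 msi2 msi3 at 20 days (1017) and hag2 msi2 msi3 against msi2 msi3 (281).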
